A study of Mus musculus with 12 samples.

How the data were processed

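Muscle RNA from 12 mice of 16 weeks was hybridised to 12 one-colour Affymetrix arrays after biotin labelling, per the labels. The groups were wild type and GPR120 KO, each on a normal or a high fat diet, with 3 mice per group. RNA was isolated with guanidine, phenol and chloroform, per the labels. Sex, batch, muscle site and time of dissection are not given in the sources used here. The mouse numbers of the groups cover different ranges, so group cannot be told apart from cohort or litter, and they allow no pairing.

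The deposited values are log2 signals that the authors computed with MAS5, per the submitters' processing notes; the version is not given in the sources used here. On the linear scale the 2 to 98% trimmed mean was the same on all 12 arrays. The values were used as deposited. Array medians lay between 3.87 and 4.17, and each array's mean correlation with the others of its own group was 0.959 to 0.970.

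Of 45101 probe sets, 64 controls were removed and 45037 kept. Of these, 34945 carried a single gene symbol, 932 several and 9160 none. Probe sets were kept when their mean log2 value was above the median of 3.78, which is 13.8 on the linear scale, and 22518 passed. The brightest probe set per symbol stood for its gene, which left 11345 genes.

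One linear model over the 12 arrays was fitted in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and an intensity trend (8 residual and 5.42 prior degrees of freedom). There were 7 contrasts: the diet effect in each genotype, the genotype effect on each diet, both averaged effects and their interaction. P-values were adjusted by Benjamini-Hochberg within each contrast, at a threshold of 0.05. Values are log2 differences with their SE. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

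Before any value was seen, 23 gene lists were fixed, covering cell types, fibre types, fuel metabolism, insulin signalling, atrophy, denervation, stress, interferon and the clock. Of these, 21 had the minimum of 5 tested members; brown adipocyte (4) and erythroid (2) did not. Per1 is in both the atrophy and the circadian list. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Members past the threshold were counted over all genes and adjusted over the list alone.

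Genes named in the text follow a rule fixed before any value was seen. It takes fatty acid receptors and sex chromosome genes in every group, and up to 12 genes per direction in each simple effect, with the largest change among those past the threshold whose groups do not overlap. It takes up to 8 per direction in the averaged effects and the interaction, leading and passing members of each list that passed, at most 2 members of other lists, and genotype calls within 10 Mb of Ffar4. Exceptions are marked as chosen after their values were seen.

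On simulated data with 11345 genes, the diet effect in wild type recovered 26.9% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 95.5% of those changed 4-fold. The interaction recovered 2.99%, 38.8% and 68.2%. Unchanged genes called numbered 2 and 3. In these simulations, with 67, 67 and 66 genes changed at the 3 sizes, a change of 1.5-fold was therefore mostly missed. The share recovered depends on how many genes change, and the real diet effect in wild type called 687. The averaged effects were not simulated. In the real averaged diet effect, 657 of 1552 called genes reached 1.5-fold and the rest were smaller.

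The arrays were regrouped in all 10 ways for each simple effect. For the averaged effects, the interaction and the correlations 100 regroupings were used, the real one and random draws with a fixed seed. Clustering of calls was tested by the number of called pairs within 1 Mb against 10000 random draws, with neighbours taken from GRCm38.p6. Alternatives were offsets at the 10th and 50th percentile of linear values, other filters, quantile normalization, median centring, all probe sets, no intensity trend, array weights, the 3′ over 5′ ratio as a covariate, only the groups compared, and each mouse left out in turn. The covariate as an alternative for every gene list was added after seeing the data.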

Results

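Skeletal muscle RNA of 12 mice was measured, 3 in each of 4 groups that crossed genotype with diet. GPR120, the product of the gene Ffar4, is a cell-surface receptor for long-chain fatty acids. By the labels, the knockout (KO) mice lacked it, and their wild-type (WT) counterparts carried it. All were 16 weeks old, on a mixed 129/Sv and C57BL/6 background, and ate a normal diet or a high fat diet. The series title ties the receptor to obesity on a high fat diet, so the comparisons ask how muscle transcripts changed with the diet in each genotype, how the genotypes differed on each diet, and whether the diet effect depended on genotype. The values are deposited log2 array signals of 45101 probe sets, from which 11345 genes were tested. With 3 arrays per group, the number of arrays limits the precision of every value.

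Ffar4 itself was too dim to check the genotype labels, and its means were not lower in KO. Its only probe set averaged 1.61 on the log2 scale, at the 20.1th percentile of all probe sets, below the signal filter. The group means were 0.23 ± 1.86 in WT on normal diet, 1.41 ± 0.93 in WT on high fat diet, 2.48 ± 1.89 in KO on normal diet and 2.31 ± 1.18 in KO on high fat diet (SD, n = 3). Whether that probe set lies in the deleted part is not given in the sources used here. Among other fatty acid receptors, Gpr84, a receptor for medium-chain fatty acids, also stayed below the filter at 1.51. Ffar2, a short-chain fatty acid receptor, averaged 4.62 and rose with the high fat diet in KO muscle (log2 difference 2.08, adjusted p = 0.0485). Ffar1, Ffar3 and Gpr119 were not named for a single-gene probe set in the annotation used. The Y-linked genes Eif2s3y, Kdm5d and Uty averaged 8.88, 6.42 and 5.68, while Xist averaged 3.32 and did not pass the filter. The arrays' highest Xist value was 4.46 and the lowest Eif2s3y value 8.48.

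Control probe sets moved with the groups. The mean 3′ over 5′ log2 ratio of beta-actin and Gapdh, a sign of RNA integrity, was −0.02 ± 0.09 in WT on normal diet, 0.18 ± 0.02 in WT on high fat diet, 0.07 ± 0.06 in KO on normal diet and 0.16 ± 0.13 in KO on high fat diet (SD, n = 3). It was 0.14 higher on high fat diet than on normal diet (exact permutation test of 6 against 6 arrays, two-sided, p = 0.0238, adjusted over 6 such tests 0.0476). The shift lay mainly in beta-actin, at 0.22 in WT and 0.39 in KO on normal diet, and 0.60 and 0.55 on high fat diet. Gapdh hardly moved, at −0.26 in WT and −0.24 in KO on normal diet, and −0.25 and −0.22 on high fat diet. Spiked hybridisation controls were 0.15 higher on high fat diet (exact permutation p = 0.00649, adjusted 0.0325), and poly-A spikes were 0.28 higher in KO (exact permutation p = 0.0108, adjusted 0.0325). The first principal component held 24.6% of the variance and separated the diets.

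On the high fat diet, WT muscle had higher genes for burning fat and lower atrophy and immediate early genes. The largest increases were in Aplnr, the apelin receptor (log2 difference 3.34 ± 0.31 SE, n = 3 per group, adjusted p = 9.27e-05), and Ky, a muscle protein mutated in the kyphoscoliosis mouse (2.66 ± 0.24, adjusted p = 8.04e-05). The largest decreases were in Ankrd1, a stretch-responsive repeat protein of the sarcomere (−4.23 ± 0.78, adjusted p = 0.00865), Mmp10, a matrix metalloproteinase (−4.08, adjusted p = 0.0447), Plet1 (−4.05) and Depp1 (−3.97 ± 0.51, adjusted p = 0.00100), a target of FoxO transcription factors. Hspb7, a small heat shock protein of striated muscle, fell by 2.98 (SE 0.26, adjusted p = 5.84e-05), and Tmem87a fell by 2.72 (adjusted p = 2.23e-05). Each of these set 1 group apart. Hspb7 read 9.48 to 9.63 in the WT mice on high fat diet and 11.83 to 13.17 in all others. Tmem87a read 8.21 to 8.31 in the WT mice on normal diet and 4.88 to 5.86 in all others. For both genes, as for all diet effects here, diet cannot be told apart from cohort. In all, 687 of 11345 genes passed an adjusted p of 0.05 in limma, 348 higher and 339 lower, with a median absolute log2 difference of 0.76 among them.

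Fatty acid uptake and oxidation was the clearest rising group in WT. Of its 27 tested members 15 rose, 0 fell and 12 did not pass, and 19 rose when adjusted over the list alone (camera adjusted p = 2.01e-14, and adjusted p = 0.0355 with an estimated correlation). Fabp3, the muscle fatty acid binding protein, rose by 0.97 (SE 0.10, adjusted p = 0.000220). Ech1 rose by 0.89, the dienoyl-CoA reductase Decr1 by 0.89 and the thiolase Acaa2 by 0.94. Oxidative phosphorylation genes were higher too: 7 of 29 rose and 24 did so adjusted over the list alone. Their differences were small, such as 0.34 for Sdhb and 0.36 for Atp5c1 (camera adjusted p = 2.77e-12, but adjusted p = 0.146 with an estimated correlation). In the citric acid cycle and mitochondrial biogenesis list 5 of 16 rose, among them Idh2 (0.95, adjusted p = 0.000323) and the coactivator Ppargc1a (0.87), with 8 higher adjusted over the list alone (camera adjusted p = 6.08e-06, adjusted p = 0.136 with an estimated correlation). Idh2 also set 1 group apart, at 8.84 to 9.06 in WT on normal diet and 9.74 to 10.09 in all other mice. Slow fibre genes had 3 of 13 higher, led by Myl3 (0.53). There were 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000474, adjusted p = 0.277 with an estimated correlation). The fast fibre list (0 of 13 past over all genes, 3 higher adjusted over the list alone, camera adjusted p = 0.00121) and the glycolysis and glycogen list (1 of 17, Pgam2 at 0.33, 3 higher adjusted over the list alone, camera adjusted p = 0.0450) tested higher. They had adjusted p = 0.510 and 0.605 with an estimated correlation.

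The falling side in WT was led by the atrophy and glucocorticoid response list, in which 14 of 19 members fell, 0 rose and 5 did not pass (17 fell adjusted over the list alone; camera adjusted p = 1.89e-18, and adjusted p = 0.0355 with an estimated correlation). Both muscle ubiquitin ligases fell, Trim63 (MuRF1) by 0.80 and Fbxo32 (atrogin-1) by 1.25. So did Cebpd (−2.71), Ddit4 (−3.04), Tsc22d3 (−1.10) and Fkbp5 (−1.28), genes known to respond to glucocorticoids. Of 17 immediate early genes 10 fell and 0 rose, among them Maff (−2.47), Btg2 (−2.31), Egr1 (−1.93) and Fos (−1.44). 13 fell adjusted over the list alone (camera adjusted p = 1.65e-11, adjusted p = 0.0433 with an estimated correlation). Heat shock and unfolded protein response genes had 7 of 18 lower and 1 higher, with Dnajb1 at −3.03 and Hspa1a at −2.38, while Ddit3 rose by 0.72. Adjusted over the list alone 10 were lower and 1 higher (camera adjusted p = 6.08e-06, adjusted p = 0.146 with an estimated correlation). In the insulin signalling and glucose uptake list Tbc1d1 (−0.78) and the glucose transporter Slc2a1 (−0.84) fell while Tbc1d4 rose by 1.40. Over 21 members 3 were higher and 8 lower adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.0433 with an estimated correlation). The denervation and regeneration list tested lower (camera adjusted p = 0.00619, adjusted p = 0.0599 with an estimated correlation): Gadd45a (−1.74), Runx1 (−2.13) and Cdkn1a (−2.13) fell, Pax7, the satellite cell factor, rose by 2.02, and 1 was higher and 6 lower of 11 adjusted over the list alone.

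The remaining groups had few members past the threshold in WT. Macrophage and inflammation genes had 0 of 13 past the threshold, over all genes or adjusted over the list alone, with Cd68 at −1.19 (adjusted p = 0.0889). Their test was lower at a camera adjusted p of 0.0159 and lost with an estimated correlation (adjusted p = 0.448). The Schwann cell and nerve list had 0 of 8 past either way, with Mal at −0.94 (camera adjusted p = 0.0321, adjusted p = 0.146 with an estimated correlation). Lists with no camera call in WT were extracellular matrix and fibroblast (1 of 22 lower, Lox at −1.58), fatty acid and triglyceride synthesis (3 of 19 higher, among them Srebf1 at 0.76), cholesterol synthesis (1 of 15 higher, Sqle at 1.62). Others were endothelium (1 of 12 higher, Kdr at 1.24), interferon response and antigen presentation (0 of 15), and lymphocyte and granulocyte (0 of 5). The circadian clock list had Dbp (1.89) and Per3 (1.55) higher among 17, and the adipocyte list had 0 of 11 past. Adipoq, the adipocyte hormone adiponectin, was at 0.07. Both of these lists had a positive median and mean but a camera direction of Down (adjusted p = 0.954 and 0.867). Of the brown adipocyte markers, 4 were measurable, too few to test as a list, and Cidea rose by 1.34.

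The WT diet count depended on single mice. It was 199 without WT normal diet replicate 2, 256 without WT normal diet replicate 3, 383 without WT high fat diet replicate 1 and 303 without WT high fat diet replicate 2. In that last case the share of higher genes went from 50.7% to 38.9%. It was 186 with the 3′ over 5′ ratio as a covariate and 383 with only these 6 arrays fitted, 160 higher and 223 lower. Median centring gave 456 higher and 321 lower. The values on the 2 diets did not overlap for 26.7% of genes in WT and 26.5% in KO, against 10% by chance.

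In KO muscle on the high fat diet single inflammatory, matrix and fat oxidation genes were higher, and single atrophy genes and chaperones lower. As lists, 12 were called, and 0 of those calls held with an estimated correlation (adjusted p = 0.0766 for atrophy, 0.102 for fatty acid oxidation, 0.230 for macrophage and for heat shock, 0.325 for matrix). Ubd, a ubiquitin-like protein induced by inflammatory cytokines, rose by 5.06 (SE 0.58, n = 3 per group, adjusted p = 0.00127). In the other 3 groups Ubd read 1.51 to 4.08, near or under the filter of 3.78, so the size of its rise is uncertain. The acute phase genes rose as well, Hp by 3.45 (adjusted p = 0.00449) and Saa3 by 3.31 (adjusted p = 0.00398), and Lgals3, the macrophage lectin galectin-3, by 2.45 (adjusted p = 0.00197). The clock output gene Dbp rose by 2.44, Aplnr by 2.32 and Mest, an imprinted gene of mesoderm that also marks expanding adipose tissue, by 2.23. Chaperones were among the largest decreases, with Dnajb1 at −3.58, Hspa1a at −3.33 and Hspa1b at −3.19. Next came Pon1 (−3.55), Depp1 (−3.14), Ddit4 (−2.99) and Arrdc3, an arrestin-like protein (−2.38 ± 0.18, adjusted p = 6.43e-05). The limma count was 515 of 11345 genes, 302 higher and 213 lower, with a median absolute log2 difference of 0.83.

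The inflammatory side in KO held 4 of 13 macrophage and inflammation genes higher and 0 lower, namely Lgals3, Saa3, Adgre1 (the macrophage antigen F4/80, 1.11) and Lyz2 (1.07). 7 were higher adjusted over the list alone (camera adjusted p = 0.000198, adjusted p = 0.230 with an estimated correlation). Interferon response and antigen presentation had 4 of 15 higher, with B2m at 0.86 and the class II genes H2-Aa at 0.91 and H2-Ab1 at 0.89. There were 10 higher adjusted over the list alone (camera adjusted p = 6.54e-07, adjusted p = 0.146 with an estimated correlation). In the extracellular matrix and fibroblast list 8 of 22 rose and 0 fell, among them Col3a1 (1.24), Postn (1.71) and Col1a1 (0.87). There were 11 higher adjusted over the list alone (camera adjusted p = 2.73e-05, adjusted p = 0.325 with an estimated correlation). Most adipocyte markers moved the same way: Fabp4 rose by 0.53 as 1 of 11 past over all genes, Adipoq was 1.71 higher (adjusted p = 0.0980) and Lep, leptin, 3.66 higher (adjusted p = 0.0995). The means of Pck1 (7.444 on normal diet, 7.044 on high fat diet) and Pnpla2 (9.998 and 9.727) went the other way. Of 11, 6 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0290, adjusted p = 0.376 with an estimated correlation). Fatty acid and triglyceride synthesis had 4 of 19 higher on both counts, over all genes and adjusted over the list alone. They included Agpat2 at 1.51, Gpam at 0.81 and Srebf1 at 0.68 (camera adjusted p = 0.00806, adjusted p = 0.238 with an estimated correlation).

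Fat oxidation genes rose in KO as well: 11 of 27 were higher, including Ech1 (0.77), Fabp3 (0.77) and Plin2, a lipid droplet coat protein (1.43). Of them 19 were higher and 2 lower adjusted over the list alone (camera adjusted p = 1.74e-09, adjusted p = 0.102 with an estimated correlation). Atrophy and glucocorticoid response genes fell in 10 of 19 cases and rose in 0, with Fbxo32 at −1.58, Trim63 at −0.79 and Cebpb at −0.91. 14 were lower adjusted over the list alone (camera adjusted p = 1.90e-17, adjusted p = 0.0766 with an estimated correlation). Immediate early genes had 5 of 17 lower, among them Btg2 (−2.09), Maff (−1.95) and Jun (−1.07). There were 8 lower adjusted over the list alone (camera adjusted p = 3.92e-08, adjusted p = 0.102 with an estimated correlation). Heat shock and unfolded protein response genes had 5 of 18 lower, and 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000101, adjusted p = 0.230 with an estimated correlation). The denervation and regeneration list had 3 of 11 lower on both counts, over all genes and adjusted over the list alone. These were Gadd45a at −1.33, Cdkn1a at −2.55 and Myog, a muscle differentiation factor, at −1.23 (camera adjusted p = 0.0127, adjusted p = 0.102 with an estimated correlation). In the insulin list the insulin receptor substrate Irs2 fell by 1.34 and Grb14, an inhibitor of the insulin receptor, rose by 0.74. These were the 2 members past the threshold by either adjustment (camera adjusted p = 0.0187, lower, and adjusted p = 0.143 with an estimated correlation). The fast fibre list had 0 of 13 past by either adjustment and tested higher (camera adjusted p = 0.0187, adjusted p = 0.635 with an estimated correlation).

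Oxidative phosphorylation had 0 of 29 past the threshold in KO (median log2 difference 0.05, camera adjusted p = 0.340), and the citric acid cycle list had 1 of 16, Ppargc1b at 0.90 (camera adjusted p = 0.819). The slow fibre list had Casq2, the slow muscle calsequestrin, higher by 1.08 (camera adjusted p = 0.0929), and the circadian list had 3 of 17 higher and 2 lower, including Nfil3 at −1.57 (camera adjusted p = 0.772). The endothelium list had 1 of 12 lower, Flt1 at −0.78, and cholesterol synthesis, Schwann cell and nerve, glycolysis and glycogen, and lymphocyte and granulocyte had 0 past the threshold. The last of these had a median of −0.03, a mean of 0.16 and a camera direction of Down. Glycolysis had a median of 0.03, a mean of −0.0013 and a direction of Up (camera adjusted p = 0.983 for each). The KO count was 200 without KO normal diet replicate 1, 133 without KO normal diet replicate 2, and 255, 312 and 158 without KO high fat diet replicates 1, 2 and 3. It was 264 with the 3′ over 5′ ratio as a covariate and 881 with array weights. Median centring turned its split from 58.6% higher to 45.5%, and leaving out KO high fat diet replicates 1 or 3 gave 44.3%.

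**Figure D1:**
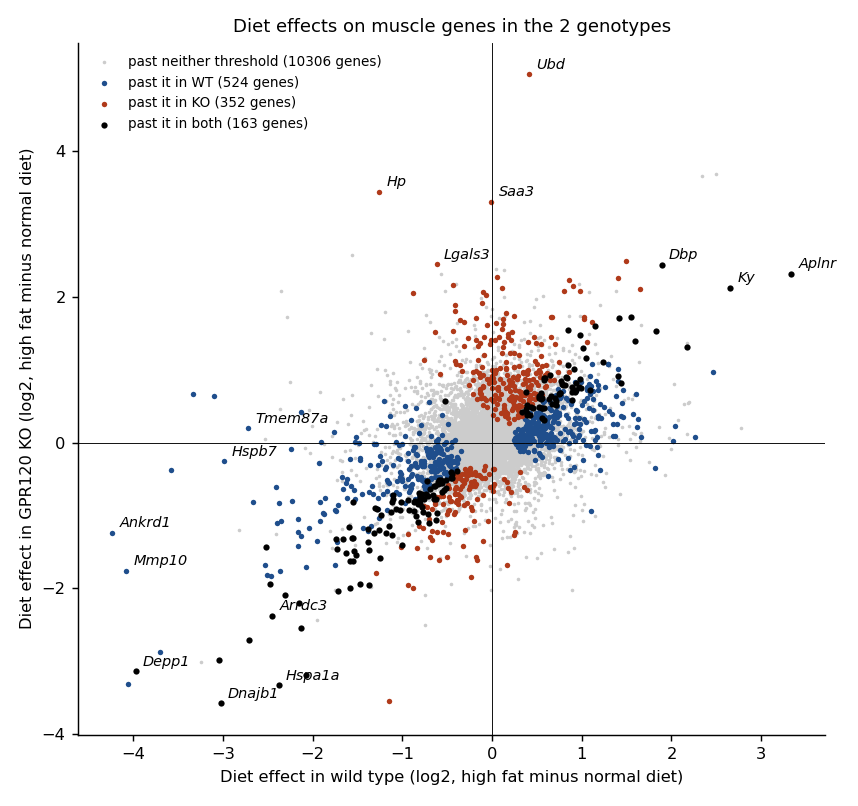
Each point is 1 of 11345 genes, with its log2 difference between high fat and normal diet in wild type on the horizontal axis and in GPR120 KO on the vertical axis. Colours mark genes past an adjusted p of 0.05 in limma in either or both genotypes, with the number of genes in the key. Depp1, Dnajb1, Aplnr, Ky and Dbp lie near the diagonal, Ubd (5.06) and Hp (3.45) are high in KO alone on the vertical axis, and Hspb7 (−2.98) and Tmem87a (−2.72) are low on the horizontal axis.

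The diet effects of the genotypes share no arrays. Across genes, which are not independent replicates, their log2 differences correlated with r = 0.390, and with r = 0.113 without the intensity filter. Of the 1039 genes past the threshold in either genotype 85.4% had the same sign in both, 67 were higher in both against 9.26 expected from independent lists, 95 were lower in both against 6.37, and 1 went opposite ways. Averaged over genotypes, 1552 genes passed, 850 higher and 702 lower. Aplnr (2.83 ± 0.22, adjusted p = 1.51e-05), Ky (2.39, adjusted p = 6.68e-06), Dbp (2.17) and Per3 (1.64) rose. Plet1 (−3.68), Depp1 (−3.55), Dnajb1 (−3.30), Sox9 (−3.29), Ddit4 (−3.02) and Hspa1a (−2.85) fell. The count was 513 with the 3′ over 5′ ratio as a covariate, 230 higher and 283 lower, and 1021 without WT normal diet replicate 2, and 657 genes also reached a 1.5-fold change.

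In this averaged effect 17 of 19 atrophy and glucocorticoid response genes fell over all genes and adjusted over the list alone (camera adjusted p = 3.82e-21). Of 27 fatty acid oxidation genes 18 rose and Pdk4, an inhibitor of pyruvate dehydrogenase, fell by 0.24 (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.42e-13). Of 17 immediate early genes 11 fell (12 adjusted over the list alone, camera adjusted p = 2.72e-12). These calls held with an estimated correlation (adjusted p = 0.0323 for each). So did those of the insulin signalling list (2 of 21 higher and 5 lower, 2 and 8 adjusted over the list alone, camera adjusted p = 0.000662) and the denervation and regeneration list (0 higher and 3 lower of 11, 1 and 4 adjusted over the list alone, camera adjusted p = 0.00176), both at adjusted p = 0.0323. In WT alone the atrophy, fatty acid oxidation, immediate early and insulin calls held. In KO alone and in the genotype and interaction comparisons 0 list calls did. The other calls were lost. They were oxidative phosphorylation (8 of 29 higher, 18 adjusted over the list alone, camera adjusted p = 5.8e-07, adjusted p = 0.295 with an estimated correlation) and heat shock (1 of 18 higher and 10 lower by either adjustment, camera adjusted p = 3.38e-06, adjusted p = 0.156 with an estimated correlation). Interferon response was another (5 of 15 higher, Ifit2 at 0.85 and Oasl2 at 1.11 among them, 10 adjusted over the list alone, camera adjusted p = 0.000102, adjusted p = 0.241 with an estimated correlation). Also lost were fast fibre (Casq1, 0.22, 1 of 13 by either adjustment, camera adjusted p = 0.000806, adjusted p = 0.443 with an estimated correlation) and slow fibre (4 of 13 higher, Casq2 at 0.79, 9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00201, adjusted p = 0.329 with an estimated correlation). The same held for citric acid cycle (3 of 16 higher, 4 adjusted over the list alone, camera adjusted p = 0.00201, adjusted p = 0.295 with an estimated correlation). Fatty acid synthesis (5 of 19 higher by either adjustment, Srebf1 at 0.72, camera adjusted p = 0.0369, adjusted p = 0.329 with an estimated correlation) and Schwann cell and nerve (1 of 8 lower by either adjustment, Mal at −0.84, camera adjusted p = 0.0440, adjusted p = 0.232 with an estimated correlation) were lost as well. The adipocyte, cholesterol synthesis, circadian, endothelium, extracellular matrix, glycolysis, lymphocyte and macrophage lists had no averaged call (camera adjusted p = 0.101 to 0.894). The 3′ over 5′ ratio, which rises with the diet, stood beside these changes. With it as a covariate, an alternative run for the lists after seeing the data, fatty acid synthesis and slow fibre lost their averaged calls (adjusted p = 0.333 and 0.0539). This covariate also removed 1 of 12 list calls for the diet in KO, 1 of 8 for genotype on normal diet and 2 of 8 for the averaged genotype effect. None was lost for the diet in WT, genotype on high fat diet or the interaction.

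On the normal diet, KO and WT muscle differed in few genes. Cntnap2, a neuronal adhesion protein, was 2.48 higher in KO (SE 0.49, n = 3 per group, adjusted p = 0.0466), the replication gene Mcm6 2.47 higher (adjusted p = 0.0370) and Aplnr 1.64 higher (adjusted p = 0.0394). Tmem87a was lower by far the largest margin, at −3.16 ± 0.20 (adjusted p = 4.03e-06), followed by the NADPH oxidase Nox4 (−1.53), the death receptor Fas (−1.26), Tmem242 (−1.24) and Dpf3 (−1.23). Idh2 rose by 0.87 (adjusted p = 0.00286), and Plce1 (1.16) and Myog (1.13) were also higher. On the high fat diet KO differed from WT by only −0.25 in Tmem87a and −0.0069 in Idh2. Both genes set WT on normal diet apart from all other groups, so genotype cannot be told apart from cohort for them. The limma count was 47 of 11345 genes, 33 higher and 14 lower, and 1277 genes had an unadjusted p under 0.05. Groups did not overlap for 17.0% of genes, against 10% by chance.

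Slow fibre genes were higher in KO on the normal diet: Myl3, the slow muscle myosin light chain, rose by 0.73 as 1 of 13 over all genes, and 7 rose adjusted over the list alone (camera adjusted p = 8.54e-07, adjusted p = 0.427 with an estimated correlation). Fatty acid oxidation tested higher with 0 of 27 past over all genes and 5 higher adjusted over the list alone (Fabp3 at 0.44, camera adjusted p = 0.00228, adjusted p = 0.452 with an estimated correlation). So did citric acid cycle with 1 of 16, Idh2, by either adjustment (camera adjusted p = 0.00147, adjusted p = 0.452 with an estimated correlation). Oxidative phosphorylation tested higher with 0 of 29 past by either adjustment (Ndufs3 at 0.21, camera adjusted p = 0.0174, adjusted p = 0.820 with an estimated correlation). Tested lower were atrophy (0 of 19, 1 lower adjusted over the list alone, Cebpb at −0.48, camera adjusted p = 0.000109, adjusted p = 0.452 with an estimated correlation) and macrophage and inflammation (0 of 13 by either adjustment, Lyz2 at −0.73, camera adjusted p = 0.00228, adjusted p = 0.452 with an estimated correlation). Also lower were insulin signalling (0 of 21, 1 lower adjusted over the list alone, the insulin receptor Insr at −0.45, camera adjusted p = 0.0252, adjusted p = 0.427 with an estimated correlation) and glycolysis (0 of 17 by either adjustment, Pgk1 at −0.29, camera adjusted p = 0.0373, adjusted p = 0.820 with an estimated correlation). The other 13 lists had no camera call on this diet. Of their members Myog passed, and Ighm, an antibody heavy chain, stood at −1.44 (adjusted p = 0.0580). In that set the fast fibre, fatty acid synthesis, immediate early, and lymphocyte and granulocyte lists had medians and means of different sign or against the camera direction. The count of 47 was 9 without WT normal diet replicate 2, KO normal diet replicate 2 or KO normal diet replicate 3, and 15 without WT normal diet replicate 3 or KO normal diet replicate 1. It was 25 with the 3′ over 5′ ratio as a covariate and 90 with array weights. The split of 33 higher and 14 lower became 24 and 26 with only these 6 arrays fitted, and 4 and 5 without KO normal diet replicate 3.

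On the high fat diet, single inflammatory and collagen genes were higher in KO than in WT muscle. As lists, macrophage (2 of 13 past) and matrix (6 of 22 past) tested higher beside the adipocyte list (camera adjusted p = 0.00500), and none of these calls held (adjusted p = 0.319, 0.319 and 0.376 with an estimated correlation). Ubd was 4.60 higher (SE 0.58, n = 3 per group, adjusted p = 0.00373), Hp 4.57 higher (SE 0.55, adjusted p = 0.00311), and Lgals3 2.28 higher (adjusted p = 0.00539). Ubd read 2.74 to 4.08 in WT, near or under the filter of 3.78, so the size of its difference is uncertain. The macrophage protein Cd68 was 2.10 higher (adjusted p = 0.0311) and the matrix protein Postn 2.17 higher (adjusted p = 0.0277). Hspb7 was 3.12 higher (SE 0.26, adjusted p = 0.000133), with group means of 12.66 in KO and 9.54 in WT. Lower in KO were Tmem100 (−2.10, adjusted p = 0.00388), Rbp7 (−2.03), Neto2 (−1.95), Chac1, a glutathione-degrading stress enzyme (−1.53, adjusted p = 0.00388), and the haem exporter Flvcr1 (−1.22, adjusted p = 0.00311). The limma count was 83 of 11345 genes, 58 higher and 25 lower, and 1681 had an unadjusted p under 0.05. Groups did not overlap for 19.4% of genes, against 10% by chance.

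Extracellular matrix and fibroblast genes led the groups: 6 of 22 rose and 0 fell, namely Col1a1 (1.47), Col3a1 (adjusted p = 0.0238), Postn, Col5a2 (1.28), Sparc (1.02) and Col6a2 (1.14). In all 15 rose adjusted over the list alone (camera adjusted p = 1.81e-13, adjusted p = 0.319 with an estimated correlation). Of 13 macrophage and inflammation genes 2 rose, Lgals3 and Cd68, and 6 adjusted over the list alone (camera adjusted p = 5.08e-06, adjusted p = 0.319 with an estimated correlation). Adipocyte markers moved with both groups: the list tested higher with 0 of 11 past over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00500, adjusted p = 0.376 with an estimated correlation). Adipoq was at 12.07 ± 0.32 in KO against 10.66 ± 0.92 in WT (log2 difference 1.41, adjusted p = 0.257), Cidec 1.92 higher and Nnat 1.95 higher (adjusted p = 0.0672). Fatty acid synthesis had 0 of 19 past, Fasn at 1.40, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.376 with an estimated correlation). Interferon response (0 of 15, 5 higher adjusted over the list alone, H2-Aa at 0.73, camera adjusted p = 0.0232, adjusted p = 0.472 with an estimated correlation) tested higher. So did Schwann cell and nerve (0 of 8, 2 higher adjusted over the list alone, S100b at 1.16, camera adjusted p = 0.0232, adjusted p = 0.319 with an estimated correlation). Slow fibre genes had Casq2 higher by 1.03 as 1 of 13 by either adjustment (camera adjusted p = 0.0175, adjusted p = 0.472 with an estimated correlation).

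The oxidative phosphorylation, glycolysis and citric acid cycle lists tested lower in KO on the high fat diet, with 0 genes past the threshold over all genes and 0 calls held with an estimated correlation. Oxidative phosphorylation had 0 of 29 past by either adjustment and a median of −0.11 (camera adjusted p = 2.93e-07, adjusted p = 0.376 with an estimated correlation). Glycolysis and glycogen had 1 higher and 7 lower of 17 adjusted over the list alone, with Pgm1 at −0.46 and Pkm at −0.33 (camera adjusted p = 1.03e-05, adjusted p = 0.376 with an estimated correlation). The atrophy list (0 of 19, 1 lower adjusted over the list alone, Eif4ebp1 at −0.51, camera adjusted p = 0.0258, adjusted p = 0.472 with an estimated correlation) and the citric acid cycle list (0 of 16, 1 higher and 2 lower adjusted over the list alone, Pdha1 at −0.24, camera adjusted p = 0.0407, adjusted p = 0.472 with an estimated correlation) were lost without single mice and with quantile normalization. Among lists with no call, Ier2 (1.41) and Egr1 (1.65) of the immediate early genes and Sdf2l1 (1.33) of the unfolded protein response were higher, while Chac1 (−1.53) of the same list as Sdf2l1 was lower. Fatty acid oxidation had a positive median and mean but a camera direction of Down (adjusted p = 0.855). The count of 83 was 15 without KO high fat diet replicate 1, 25 without KO high fat diet replicate 3, 23 and 21 without WT high fat diet replicates 1 and 3, and 237 without WT high fat diet replicate 2. It was 29 with only these 6 arrays fitted, 163 with a larger offset, and 140 with median centring, where 39.3% were higher against 69.9%.

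**Figure D2:**
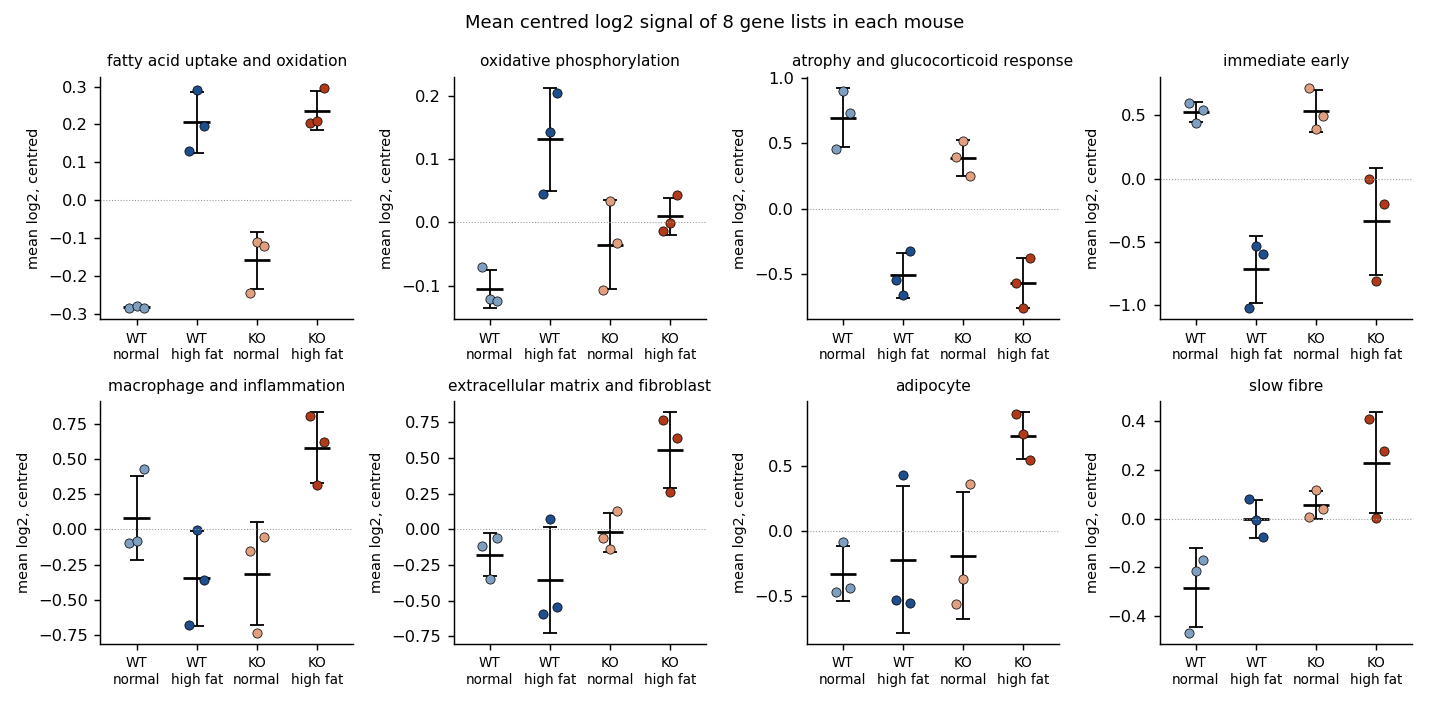
Each panel shows 1 gene list. A point is 1 mouse's mean log2 signal over the list's tested genes after subtracting each gene's mean over the 12 arrays, and bars give the group mean ± SD (n = 3). Atrophy and immediate early scores are lower on high fat diet in both genotypes, and the KO mice on high fat diet have the highest group means for the macrophage, extracellular matrix, adipocyte and slow fibre lists.

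Averaged over diets, 183 genes differed by genotype, 102 higher and 81 lower in KO. Col1a1 (adjusted p = 0.00756), Rab6b (4.30, adjusted p = 0.0268), the zinc finger gene Zfp52 (2.16), Mybph, a myosin binding protein (1.19), and Pla2g7 (1.07) rose. Neto2 (−1.79), the mast cell tryptase Tpsab1 (−1.37), Chac1 (−1.22) and Tmem242 (−1.18, adjusted p = 0.00166) fell. Matrix genes had 6 of 22 higher and 14 adjusted over the list alone (camera adjusted p = 6.32e-09). Slow fibre genes had 4 of 13 higher, Casq2 at 0.74 and Myh7 at 0.40 among them, and 7 adjusted over the list alone (camera adjusted p = 2.53e-06). Glycolysis had Pgk1 lower (−0.26) and 5 lower of 17 adjusted over the list alone (camera adjusted p = 1.49e-05). Atrophy had Cebpb lower (−0.40) and 5 of 19 lower adjusted over the list alone (camera adjusted p = 8.06e-05). Pmp22 rose by 0.46 in the Schwann cell list (3 of 8 higher adjusted over the list alone, camera adjusted p = 0.0411), and Insr fell by 0.34 in the insulin list (2 of 21 lower adjusted over the list alone, camera adjusted p = 0.0458). All of these 6 list calls were lost, at adjusted p = 0.291 with an estimated correlation. Adipocyte markers (Nnat at 1.52, 1 of 11 higher by either adjustment, camera adjusted p = 0.0458) and fatty acid synthesis (Me1 at 0.89, 1 of 19 higher, 6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0458) tested higher, with adjusted p = 0.526 and 0.514 with an estimated correlation. In the lymphocyte and granulocyte list Ighm fell by 1.17 while the list's median and mean were positive and its camera direction Down. The circadian list also had a positive median and mean and a direction of Down.

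Genes near Ffar4 were over-represented among the genotype calls. Within 10 Mb of it, by gene order and distance in GRCm38.p6, 7 of 148 tested genes (4.73%) passed, against 176 of 11165 elsewhere (1.58%; Fisher's exact test, one-sided, p = 0.0102). They were Plce1, the retinol binding protein Rbp4 (1.15), Pik3ap1 (1.42), the smooth muscle actin Acta2 (0.69) and Marveld1 (0.45), which rose, and Aldh18a1 (−1.15) and Noc3l (−0.77), which fell. Genotype effects on the normal and the high fat diet, which share no arrays, correlated with r = 0.165 across genes, and r = 0.044 without the intensity filter. There were 2 genes higher in both, 1 lower in both and 0 opposite among the 127 past in either. The averaged count was 66 without WT normal diet replicate 2 and 287 without WT high fat diet replicate 2, where 67.9% were higher against 55.7%. It was 101 without WT high fat diet replicate 1, 121 without WT high fat diet replicate 3, 110 and 92 without KO normal diet replicates 1 and 3, 78 without KO high fat diet replicate 1, and 104 with the 3′ over 5′ ratio as a covariate. Median centring gave 39.3% higher.

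The diet effect itself differed between genotypes for 16 genes, 9 with a larger and 7 with a smaller value in KO, and 1178 genes had an unadjusted p under 0.05. Ctss, the lysosomal protease cathepsin S of antigen-presenting cells, went from −0.11 in WT to 1.92 in KO (difference 2.03 ± 0.24, adjusted p = 0.00602). Lgals3 went from −0.61 to 2.45 (3.06, adjusted p = 0.0179), Gpnmb, a glycoprotein of lipid-laden macrophages, from −0.63 to 1.52 (2.15, adjusted p = 0.0179). Hp went from −1.26 to 3.45 (4.71, adjusted p = 0.0362) and Ubd from 0.41 to 5.06 (4.64, adjusted p = 0.0484). The size for Ubd is uncertain, since outside KO on high fat diet its signal was near or under the filter. Hspb7 fell in WT and was −0.26 in KO (2.73, adjusted p = 0.00972), and Tmem87a fell in WT and was 0.19 in KO (2.92, adjusted p = 0.000836). Going the other way were Capn3, the muscle protease calpain 3, at 1.13 in WT and 0.16 in KO (−0.97, adjusted p = 0.00912), and Idh2 at 0.95 and 0.08 (−0.88, adjusted p = 0.0365). By list, macrophage and inflammation genes had a median difference of 1.05 (1 of 13 higher, 6 adjusted over the list alone, camera adjusted p = 7.82e-09, adjusted p = 0.357 with an estimated correlation). Oxidative phosphorylation genes had one of −0.20 (0 of 29 past by either adjustment, camera adjusted p = 3.96e-09, adjusted p = 0.447 with an estimated correlation). Matrix genes had a median of 0.64 (0 of 22 past by either adjustment, camera adjusted p = 2.68e-08, adjusted p = 0.447 with an estimated correlation). Citric acid cycle genes had one of −0.19 (Idh2 lower as 1 of 16, 3 adjusted over the list alone, camera adjusted p = 2.83e-05, adjusted p = 0.447 with an estimated correlation). Interferon response stood at 0.48 (0 of 15 by either adjustment, camera adjusted p = 0.00271) and fatty acid oxidation at −0.13 (0 of 27, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00839), both at adjusted p = 0.548 with an estimated correlation. Adipocyte markers stood beside these at a median of 0.49 (0 of 11 by either adjustment, camera adjusted p = 0.0409, adjusted p = 0.556 with an estimated correlation). The heat shock list had a median of 0.07 and a mean of −0.017. The count was 31 without WT high fat diet replicate 2, between 4 and 8 without each of 9 other mice, and 1 without an intensity trend. Median centring gave 44.4% higher against 56.3%.

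**Figure D3:**
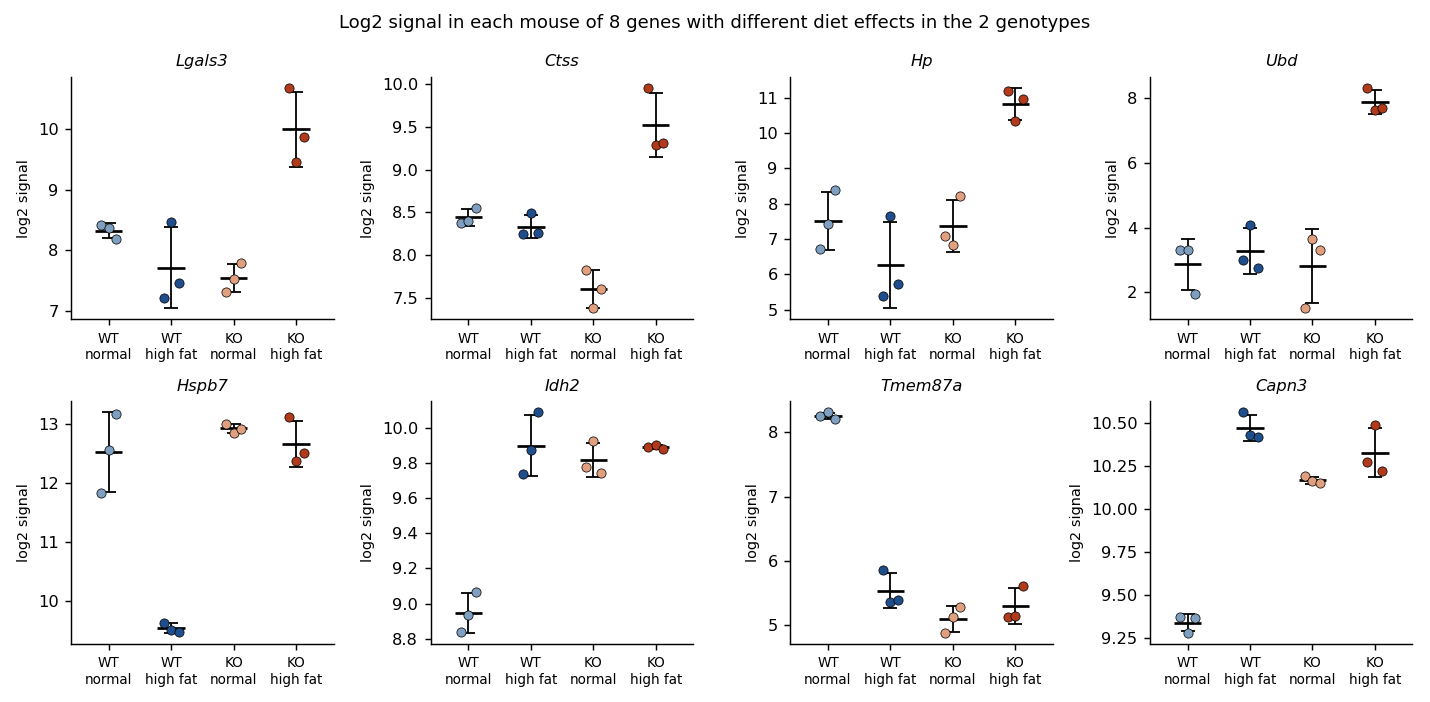
Each panel shows the log2 signal of 1 gene in every mouse by group, with group mean ± SD (n = 3), for 8 of the 16 genes whose diet effect differed between genotypes. Lgals3, Ctss, Hp and Ubd are highest in KO on high fat diet, Hspb7 is low in WT on high fat diet alone (9.54 ± 0.08 SD), and Idh2, Tmem87a and Capn3 set WT on normal diet apart from the other 3 groups.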

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

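The tests of clustering along the genome and the covariate as an alternative for every gene list were chosen only after the result was seen. The patterns weighed were picked after single-gene results were seen, and their tests were set before the test values were. The results here stand out because the diet effect differed between the genotypes; each value is the diet effect in KO minus that in wild type, in log2. For 16 genes this difference passed the threshold. The larger values in KO were Hp 4.71, Ubd 4.64, Lgals3 3.06, Tmem87a 2.92, Hspb7 2.73, Gpnmb 2.15, Ctss 2.03, Net1 1.59 and Vamp7 0.79. The smaller values were Mpp3 −1.51, A930005H10Rik −1.01, Capn3 −0.97, Me3 −0.97, Neat1 −0.95, Idh2 −0.88 and Oip5os1 −0.70. By list, the median difference was 1.05 for macrophage and inflammation, 0.64 for extracellular matrix and fibroblast, 0.49 for adipocyte and 0.48 for interferon response and antigen presentation. It was −0.20 for oxidative phosphorylation, −0.19 for the citric acid cycle and −0.13 for fatty acid oxidation. With an estimated correlation 0 of these 7 lists passed, at adjusted p = 0.357 to 0.556.

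Macrophage and inflammation genes were higher in KO than in wild type on the high fat diet, with a median of 0.66. Of 13 members 12 were positive, 2 passed over all genes and 6 adjusted over the list alone, but the list call is lost (adjusted p = 0.319 with an estimated correlation). With the 3′ over 5′ ratio as a covariate the median was 0.61. That ratio averaged 0.164 in KO and 0.175 in wild type on this diet, so the covariate could hardly move the median. This measure of RNA quality thus differed little between the groups compared, and other differences in RNA quality were not tested. Poly-A spikes averaged 8.70 in KO and 8.46 in wild type on this diet, and their bearing on the list was not tested. Fat carried in with the muscle may contribute: the 95% interval of the Adipoq difference runs from 0.21 to 2.60, so a fat-derived rise as large as that of the list is not excluded. A response of the muscle to losing GPR120 on this diet is the biological alternative. A difference of cohort, litter or strain origin between these groups is another possibility, since group cannot be told apart from cohort. The arrays cannot separate these.

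The knockout was made on a mixed background, so genotype calls could reflect strain variants near Ffar4. Of the genes within 10 Mb, 4.73% passed against 1.58% elsewhere (Fisher's exact test, one-sided, p = 0.0102). Genotype calls averaged over diets also clustered, with 47 pairs within 1 Mb against a median of 28 in random draws (permutation p = 0.0061). So did the interaction calls, with 3 pairs against 0 (permutation p = 0.0029). Genotype calls clustered on high fat diet (13 against 6, permutation p = 0.014) and on normal diet (5 against 2, permutation p = 0.048). The interaction calls and the normal diet calls both include the neighbours Oip5os1, Tmem87a and Capn3. Their clustering results are therefore not independent of each other. Diet calls in wild type did not, with 380 pairs against 400 (permutation p = 0.77), nor in KO, with 185 against 223 (permutation p = 0.98). So many calls could hide small regions. The wild type diet calls held a run of 6 genes with Oip5os1, Tmem87a and Capn3. They also held a longer run of 11 genes, among them Fbxo6, Mtor and Rbp7. Tmem87a, Capn3 and Oip5os1 are neighbours and set wild type on normal diet apart from the other 3 groups, which may be a strain variant carried by those mice. Idh2 (8.84 to 9.06 against 9.74 to 10.09) and Vamp7 (9.395 to 9.499 against 8.421 to 8.752) set the same mice apart. Hspb7 sets wild type on high fat diet apart. For genotype on that diet it lay in a called run with Padi2 and Efhd2, and Rbp7 in 1 with Mad2l2, Fbxo6 and Mtor. Whether strain variants account for Idh2, Vamp7, Hspb7 or Rbp7 was not tested.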

How the results depend on the processing

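The diet count in wild type, 687, was 1109 with all probe sets, 311 without an intensity trend, 186 with the 3′ over 5′ ratio as covariate and 383 with only the groups compared. Leaving out 1 mouse gave 199 (normal diet replicate 2) to 918 (normal diet replicate 1). The KO diet count, 515, was 232 without the trend, 881 with array weights and 264 with the covariate, and 133 (KO normal diet replicate 2) to 363 (replicate 3) without 1 mouse. The genotype count on normal diet, 47, was 19, 90 and 25 under the same alternatives, and 9 (wild type normal diet replicate 2) to 68 (replicate 1). On high fat diet, 83 became 163 with the offset at the 50th percentile, 140 with median centring, 7 without the trend and 29 with only the groups compared. Without 1 mouse it was 15 (KO high fat diet replicate 1) to 237 (wild type high fat diet replicate 2). The averaged diet count, 1552, was 2401 with all probe sets, 513 with the covariate and 657 with a 1.5-fold minimum, and 1021 to 1689 without 1 mouse. The averaged genotype count, 183, was 61 without the trend, 104 with the covariate and 115 with the fold minimum, and 66 to 287 without 1 mouse. The interaction count, 16, was 10 with quantile normalization, 6 with all probe sets and 1 without the trend, and 4 to 31 without 1 mouse. The correlation of diet effects was 0.113 without the filter. Apart from fewer arrays or more probe sets tested, the cause was not tested.

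Of 640 values for named genes, called or not, 154 lost their call with the covariate, 182 without the trend and 69 without the filter. Values without a call had none to lose, so the share of calls lost is larger than these counts out of 640. Zfp945 reversed from −1.18 to 1.70 in the averaged genotype effect with the larger offset, where another probe set was brightest. Ighm, −0.21 for the diet in KO, ranged from −0.62 to 0.06 (0.055) without 1 mouse, and S100a9, 0.36 for genotype on normal diet, from −0.0016 to 0.64; the cause was not tested. Tmem87a kept its interaction under every alternative, at adjusted p = 0.000155 to 0.00782. Those of Hspb7, Ctss and Capn3 were lost only without the trend. The interactions of Hp, Ubd, Lgals3 and Idh2 were lost under several, with adjusted p up to 0.139, 0.181, 0.0971 and 0.139. No list reversed, but list calls were lost when 1 mouse was left out: 3 of 13 for the diet in wild type, 5 of 12 for the diet in KO, 4 of 8 for genotype on normal diet, 6 of 11 for genotype on high fat diet, 2 of 13 for the averaged diet effect, 4 of 8 for the averaged genotype effect and 3 of 7 for the interaction. No paired analysis was possible because the labels share no replicate numbers between groups. Signals near the floor, such as those of Ffar4 and, outside KO on high fat diet, of Ubd, limit what the arrays can show.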

Other observations

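The tests of clustering along the genome and the covariate as an alternative for every gene list were chosen only after the result was seen. Clock genes moved in opposite directions with the diet, so that their list gave no call. Averaged over genotypes, 4 of 17 rose and 5 fell: Dbp (2.17), Per3 (1.64), Usp2 (0.51) and Nr1d2 (0.39) were higher, and Arntl (−1.54), Nfil3 (−0.88), Per1 (−0.80), Cry2 (−0.58) and Clock (−0.57) lower. Genes here beyond Dbp and Per3 were chosen after their values were seen. The time of dissection is not given in the sources used here.

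Per mouse, Adipoq and Lgals3 read as follows. In wild type on normal diet Adipoq ranged from 9.73 to 11.04 and Lgals3 from 8.19 to 8.42, both lowest in replicate 3. In wild type on high fat diet, by replicate, they were 10.15, 11.73 and 10.11 and 7.21, 8.47 and 7.46. In KO on normal diet they were 8.95, 10.81 and 11.32 and 7.32, 7.52 and 7.80. In KO on high fat diet they were 12.26, 12.25 and 11.70 and 10.67, 9.45 and 9.86.

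Averaged over genotypes, 11 of 17 immediate early genes fell with the diet, and of 18 heat shock genes 10 fell and 1 rose. The averaged heat shock call was lost with an estimated correlation (camera adjusted p = 0.156). The median over the 35 tested members of both lists was −0.70. With the 3′ over 5′ ratio as a covariate it was −0.69, so RNA quality as measured by this ratio is alone an unlikely cause. The shift of that ratio with the diet lay mainly in beta-actin. Different handling of 1 group would lower them in 1 genotype only. At the preset correlation both lists were lower in both genotypes, with a largest camera p of 2.89e-05, but with an estimated correlation heat shock is lost in both (adjusted p = 0.146 in wild type and 0.230 in KO) and immediate early in KO (adjusted p = 0.102). Single genes passed in both genotypes, Dnajb1 at −3.03 and −3.58 and Btg2 at −2.31 and −2.09, so handling of 1 group alone is unlikely to be the cause for these. Handling that differed by diet in both genotypes was not tested and could have the same effect, as could a biological response to the diet.

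Regrouping the arrays gave these results. Among the 10 splits of each simple effect, 1 had a count as large, the real one, and such splits cannot give a share under 0.1; the highest other counts were 2, 0, 0 and 1. Among 100 regroupings, 1 was as large for the averaged diet count (highest other 71) and 1 for the averaged genotype count (highest other 16). For the interaction count 2 were as large, and the highest other was 147 against the real 16, which points to a structure of the samples. In that regrouping the diet effects correlated with r = −0.345, so effects of the real groups left in it could give such a count. Counting the real one, 4 reached the correlation of diet effects (highest other 0.516). That of genotype effects was reached by 17, again with the real one (highest other 0.456), so it could be chance.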
